A study of Mus musculus with 8 samples.

How the data were processed

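RNA of 8 hepatocellular carcinomas from male mice without miR-122 and of liver from age-matched male mice with the floxed gene was measured on 8 Agilent arrays of 2 colours, all on 1 slide. Per the labels, RNA was isolated with miRVana and then RNeasy kits and labelled with a low-input amplification kit, the tumors with Cy5 and the control livers with Cy3. The 8 tumors were taken as independent biological replicates, and no array had the dyes swapped. Sample titles number the tumors and name no animal, so whether any tumors shared a mouse is not known from them. If the control RNA was shared between arrays, the tests leave out the spread of the control.

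The deposited scanner files give the median signal and median background of each spot as intensity, beside processed signals, also intensity, that per the file headers were background-subtracted, detrended and dye-normalized. The deposited log ratio is log10 of red over green and was exactly 0 at 24.2% to 30.4% of spots; elsewhere it differed from the processed signals by at most 4.09e-07. The submitters' processing notes name Agilent Feature Extraction 10.9, and the version per the file headers is 10.9.1.1. The plan had named mean signals, which the files do not hold, so median signals were used.

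Signals were corrected with normexp at an offset of 50 and normalized within arrays by loess, with control spots and spots flagged as outliers at weight 0 and no scaling between arrays (R 4.3.3, limma 3.58.1, data.table version 1.17.8). Control and outlier spots were then left out and the spots of a probe averaged. Channel values were taken after loess and Aquantile normalization. No spot was saturated. Each array held 59305 experimental spots of 55681 probes. Of these probes, 26582 were named through their accession in the annotation of the later assembly GRCm38.p6 and 10 kept the name in the files; 29089 had no symbol. Regions named by chromosome positions are those of the array design (mm9). No named probe measured miR-122, which was not analysed here. A search of transcripts for matches to the microRNA was not made, as no genome sequence was used here.

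A probe was tested if it was well above background on at least 4 arrays in at least 1 channel (29292 probes), and each of 14313 genes was represented by its tested probe of highest mean brightness. Of 3656 genes with 2 or more tested probes, 2 (Slc4a9 and Tpm1) had probes called in opposite directions. Probes of other genes differed in size, such as those of Slc1a2 (-2.70 to -0.38), Cd34 (0.72 to 3.11) and Birc5 (0.96 to 3.04). So did those of Prom1 (1.37 to 3.56), Dlk1 (1.15 to 2.72) and Tfrc (0.27 to 1.30). Sizes and ranks given here are those of the brightest probe. The mean log2 ratio of tumor over control was tested against 0 with limma (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1. Errors are SDs over 8 arrays. A gene not well above background in any array of 1 channel has only a bound there: the fold was taken against the higher of its own signal and the lowest signal of probes well above background, and is open to dye bias. This held in the control for 23 of the genes called higher and in the tumor for 4 of those called lower.

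For gene lists, 34 lists of 898 entries, of which 826 were tested, were written before the data were examined, as were the tests, thresholds, first alternatives and 4 relations between lists. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Genes named are the 10 largest rises and 10 largest falls with the same sign and a signal well above background on all 8 arrays, up to 4 called members of each list with the largest ratios, 17 genes fixed in advance and the 10 with the largest SD; others are given as members of a list. The channels' SDs were compared by swapping channels within arrays, and list scores were correlated with exact permutation tests.

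Alternatives were no background subtraction, an offset of 16, the processed signals, median centring, scaling between arrays, quantile normalization (for the spread of the channels alone), 2 other filters, the mean of all probes, other variance models, array weights, the row of the slide as a block, and each array left out in turn. Chosen after the data were examined were leaving out arrays 7 and 8 together, each row of the slide alone, row-centred correlations, arrays 1 and 2 averaged, and 9 further gene lists. The procedure was tested on simulated data of the same size: 1 of 67 genes shifted by 0.5 on the log2 scale was called, 63 of 67 (94.0%) shifted by 1.5 and 65 of 66 (98.5%) shifted by 3, with 1 false call. The shift of 0.5 lies below the ratio of 1 that a call requires. The simulated noise was independent between genes, with no shared control and no effect of dye or array, so it does not give the number of false calls in the real data.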

Results

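RNA from 8 hepatocellular carcinomas (HCC) was compared with liver RNA on 8 arrays of 2 colours. The tumors came from male mice without miR-122, the main microRNA of hepatocytes, and the control livers from age-matched males with a floxed, intact gene, all of mixed C57BL/6J and 129S/Svj background. Each array held 1 tumor in Cy5 and control liver in Cy3, so an effect of the dyes and an effect of the tumor have the same sign on every array. The labels do not say whether the control RNA came from 8 animals or from 1 pool. The share of probes well above background ranged from 38.5% to 51.9% in the tumor channel and from 45.1% to 54.3% in the control channel. Tumor 8 was the dimmest, with an upper quartile of the Cy5 signal of 213, against 378 to 606 for the others. Across genes, which are not independent replicates, the log2 ratios of tumor 8 correlated with those of the other tumors at a mean r of 0.528, against 0.630 to 0.741 for the others. On that array, the control channel also held skeletal muscle transcripts at a median of 3.99 on the log2 scale above the other arrays, over 37 genes of a list written after the data were seen. The number of arrays limits the precision of every value.

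The main comparison asked which genes differ between HCC of mice without miR-122 and normal liver. It covers the loss of the microRNA and tumor growth together, since no tumor-free knockout liver was among the samples. The fetal liver protein alpha-fetoprotein (Afp) rose most in the tumors, by 6.50 ± 0.92 on the log2 scale (SD, n = 8), which is 90.3-fold (adjusted p = 4.28e-07). Mup5, a major urinary protein secreted by male liver, fell most, by 6.65 ± 1.69 (100.4-fold, adjusted p = 1.01e-05). Of 14313 genes tested, 1366 (9.54%) were higher and 850 (5.94%) lower in tumor, at an adjusted p under 0.05 and at least 2-fold. Of these 2216 genes, 1771 (79.9%) had the same sign on all 8 arrays.

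The genes with the next largest rises were Mogat2, a monoacylglycerol acyltransferase (5.32 ± 0.58, 40.0-fold), and the desaturase Scd2 (5.27 ± 1.16, 38.7-fold). Spink1, a trypsin inhibitor, rose by 4.85 ± 1.20, and Esm1, a proteoglycan of endothelial cells, by 4.71 ± 1.54. Cbr3, a carbonyl reductase, rose by 4.69 ± 0.29 and had the smallest adjusted p of these genes (7.80e-09). Erich4 (4.69 ± 0.83), Igdcc4 (4.68 ± 0.47), the lipopolysaccharide receptor Cd14 (4.61 ± 0.79) and the tetraspanin Tspan8 (4.51 ± 1.62) completed the 10 largest rises. Among the genes that fell, Sult2a8, a sulfotransferase, had a log2 ratio of -6.35 ± 0.77 (81.7-fold lower). Other major urinary proteins fell with Mup5: Mup17 (-6.01 ± 1.28), Mup3 (-5.70 ± 1.30), Mup18 (-5.12 ± 0.64) and Mup6 (-4.64 ± 1.01). The remaining genes of the 10 largest falls were Cyp2c54 (-5.60 ± 1.33), the organic anion transporter Slco1a1 (-5.57 ± 0.87), the carboxylesterase Ces3a (-5.01 ± 1.75) and Rgn (-4.58 ± 1.70), which encodes regucalcin. Slco1a1 was well above background in 1 tumor and Mup6 in 4, and Igdcc4 in 5 control channels, so their ratios rest in part on signals near the floor, and so do their places among the largest changes. Mup, Cyp2c and Ces genes are near-identical copies, so the signal of 1 member can include that of others.

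**Figure D1:**
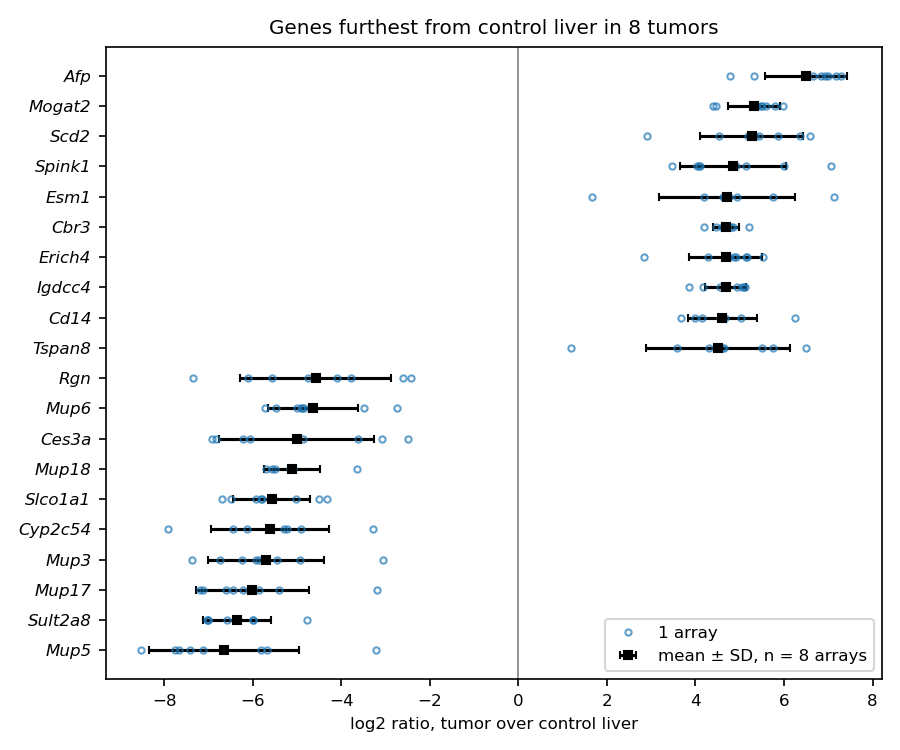
The log2 ratio of tumor over control liver (horizontal axis) is shown for the 10 largest rises and the 10 largest falls. Only called genes with the same sign and a signal well above background on all 8 arrays were eligible. Circles are single arrays and squares with bars the mean ± SD of 8 arrays. Afp lies at 6.50 and Mup5 at -6.65, and by this choice of genes every circle lies on the side of its mean.

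Genes named as targets of miR-122 rose as a group: 16 of 32 were higher and 0 lower, with a median log2 ratio of 1.07 (2.10-fold). The camera test gave an adjusted p of 6.13e-06, and an adjusted p = 0.126 with an estimated correlation. The list mean was above 0 on all 8 arrays and varied little between them (SD 0.0917). Slc7a1, an arginine transporter, rose by 2.69 ± 0.72, the glycolytic enzyme Aldoa by 2.24 ± 0.36, the filament protein Vim by 1.93 ± 0.85 and the acyltransferase Agpat1 by 1.84 ± 0.17. The transcription factor Klf6 rose by 1.73 ± 0.67 and the cyclin Ccng1 by 1.08 ± 0.43. The lipid droplet protein Cidec had a log2 ratio of 1.34 ± 2.64 and did not pass (above 0 on 6 arrays, adjusted p = 0.181). Without array 1 its ratio was 1.92 and its adjusted p 0.0484. Its control channel was high on arrays 1 and 2 (13.63 and 13.46, against 8.21 to 11.59 on the others). The tumor channel of these 2 arrays (10.86 and 12.02) lay within the range of the others (8.62 to 13.68). Adjusted over the list alone, the counts of called members were those over all genes tested in this list and in every other list, with the 3 exceptions given beside their lists.

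Genes of fetal liver and of liver cancer formed the list with the highest median of the 34 fixed lists: 14 of 24 rose and 0 fell, with a median of 1.67 (3.17-fold; adjusted p = 6.52e-08). This call had an adjusted p = 0.0938 with an estimated correlation. Beside Afp, Scd2 and Tspan8, the stem cell marker Prom1 rose by 3.56 ± 0.74. Igf2, a growth factor of the fetus, rose by 3.45 ± 0.27, and H19, the noncoding RNA transcribed next to it, by 2.75 ± 0.15. The 5 probes of H19 gave ratios from 2.75 to 5.44. Within each channel, Igf2 and H19 varied far more between arrays than their ratios did, with SDs of 1.34 and 0.82 in the tumor channel and 1.28 and 0.82 in the control channel. An effect of the array was not tested here and would change what these ratios mean. Carry-over between channels by a share common to all genes, if it set these ratios, would hold other rises near these sizes. Afp rose by 6.50 ± 0.92, which argues against such carry-over for Igf2 and H19. Carry-over limited to single probes was not tested and would also change what the ratios mean. Gpc3, a cell surface proteoglycan, had a log2 ratio of 1.41 ± 1.68 (above 0 on 6 arrays, adjusted p = 0.0396) that rested on few tumors. Its call was lost without tumor 8 (log2 ratio 0.90, adjusted p = 0.0319), and without tumor 2, 4, 5 or 6 (log2 ratio 1.29 to 1.52, adjusted p 0.0511 to 0.0879). Of the imprinted genes, 8 of 18 rose and 0 fell, with a median of 0.71 (adjusted p = 0.0120). Their adjusted p = 0.128 with an estimated correlation. They included Igf2, H19, Dlk1 (2.72 ± 2.15) and Mirg (2.40 ± 1.39), the last of which lies in the same imprinted cluster as Dlk1.

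Proliferation genes were higher in tumor: 29 of 46 cell cycle genes rose and 0 fell, with a median of 1.30 (2.47-fold; adjusted p = 1.07e-13). With an estimated correlation, the adjusted p = 0.329. The survivin gene Birc5 rose by 3.04 ± 0.51, the proliferation marker Mki67 by 2.92 ± 0.78, the replication helicase subunit Mcm6 by 2.85 ± 0.99 and the mitotic activator Cdc20 by 2.74 ± 0.86. Among p53 targets, 10 of 23 rose and 2 fell, with a median of 0.59 (adjusted p = 0.00419). With an estimated correlation, that adjusted p = 0.128. The death receptor gene Tnfrsf10b (2.68 ± 0.72), Pmaip1 (2.27 ± 0.68) and the stress hormone Gdf15 (1.81 ± 0.52) rose, while Perp fell by 2.02 ± 0.90.

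The NRF2 response to oxidants and electrophiles was higher in tumor, with 18 of 28 genes up, 0 down and a median of 1.28 (2.43-fold; adjusted p = 2.01e-06). This call had an adjusted p = 0.245 with an estimated correlation. Members that rose included Cbr3, the glutathione transferase Gsta1 (4.13 ± 0.89), one of a family of near-identical copies, the cystine transporter Slc7a11 and the efflux pump Abcc4 (3.05 ± 1.21). Slc7a11 was not well above background in any control channel and was at least 8.32-fold higher in tumor (adjusted p = 1.75e-04). The unfolded protein response list was lower as a whole, with a median of -0.51, 4 of 27 genes up and 8 down (adjusted p = 0.00927). It had an adjusted p = 0.370 with an estimated correlation. The members that rose were Atf3 (2.15 ± 0.64), Trib3 (1.48 ± 1.68), Atf4 (1.19 ± 0.39) and Ddit3 (1.02). Those that fell included Pdia6 (-1.26 ± 0.27), Pdia4 (-1.15) and Calr (-1.11). The call of Trib3 (above 0 on 7 arrays, adjusted p = 0.0325) was lost without tumor 2, 5, 7 or 8, at log2 ratios of 1.08 to 1.504 and adjusted p of 0.0561 to 0.0763. Without tumors 7 and 8 together, a choice made after the data were seen, Trib3 stood at 0.72 (adjusted p = 0.111).

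Glycolysis genes were higher, with 7 of 23 up, 1 down and a median of 0.53 (adjusted p = 0.0329; adjusted p = 0.544 with an estimated correlation). Aldoa, Pfkp (2.12 ± 1.35), the glucose transporter Slc2a1 (1.92 ± 0.89) and the lactate transporter Slc16a3 (1.65 ± 0.77) rose. The 2 tested probes of Pfkp gave ratios of 0.12 and 2.12, so its rise rests on 1 of them. This list lost its call without tumor 2 (adjusted p = 0.0580) or tumor 8 (adjusted p = 0.0594). The list mean on array 8 was 0.70, against 0.18 to 1.32 on the others. The control channel of array 8 also held muscle transcripts, and their effect on this list was not tested.

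Genes that normal liver expresses in a male pattern showed the deepest fall of any list: 18 of 22 were lower and 0 higher, with a median of -2.996 (7.98-fold lower; adjusted p = 9.68e-11). Their adjusted p = 0.0938 with an estimated correlation. Mup3, Slco1a1, Susd4 (-4.41 ± 0.55) and Ugt2b1 (-4.29 ± 1.06) fell most. The list mean lay between -3.03 and -2.60 in 7 tumors and at -1.92 in tumor 7. Genes that normal liver expresses in a female pattern were higher, with 7 of 23 up, 2 down and a median of 0.69 (adjusted p = 0.0271). They had an adjusted p = 0.300 with an estimated correlation. Of these, the lipase Lpl (3.75 ± 0.62), Prom1 and Cyp2a4 (3.14 ± 0.82) rose, and Cyp4a10 had a log2 ratio of -2.87 ± 3.53. Without tumors 7 and 8, a choice made after the data were seen, the female-biased list was no longer called (adjusted p = 0.0667).

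Detoxification genes fell: 19 of 34 members of the cytochrome P450 and conjugation list were lower and 1 higher, with a median of -1.39 (2.62-fold lower; adjusted p = 3.10e-07). With an estimated correlation, the adjusted p = 0.128. Cyp2c54, Ces3a, Ugt2b1 and Cyp2e1 (-3.84 ± 1.55) fell most, and Cyp2a4 was the member that rose. Pericentral genes, which hepatocytes around the central vein express under Wnt signals, also fell, with 16 of 24 lower (17 adjusted over the list alone), 0 higher and a median of -1.65 (adjusted p = 3.11e-05). Their adjusted p = 0.445 with an estimated correlation. Rgn, Cyp2e1, the transcription factor Tbx3 (-2.75 ± 1.63) and the glutamate transporter Slc1a2 (-2.70 ± 1.77) led this list. Its mean was 0.39 in tumor 8 and between -2.65 and -0.71 in the others. The 3 tested probes of Slc1a2 gave ratios from -2.70 to -0.38, so its place depends on the probe.

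Bile acid genes were lower, with 13 of 26 down, 2 up and a median of -0.95 (1.93-fold lower; adjusted p = 0.00150). Their adjusted p = 0.128 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.41 ± 1.83 and Cyp8b1 by 3.69 ± 1.64. The uptake transporters Slco1a1 and Slco1b2 (-3.60 ± 1.63) fell, and the basolateral efflux pump Abcc4 rose. Cholesterol synthesis genes fell too, with 12 of 25 lower, 0 higher and a median of -0.99 (adjusted p = 3.14e-06). This call had an adjusted p = 0.370 with an estimated correlation. Idi1 (-2.59 ± 0.81), Msmo1 (-1.94 ± 0.88), Tm7sf2 (-1.87 ± 0.63) and Sc5d (-1.82 ± 0.75) fell most.

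Hepatocyte identity genes were lower: 8 of 30 fell (9 adjusted over the list alone) and 0 rose, with a median of -0.83 (1.78-fold lower; adjusted p = 4.35e-06). With an estimated correlation, their adjusted p = 0.128. The nuclear receptor Nr1i3 (-2.41 ± 1.05), the tyrosine-degrading enzyme Hpd (-2.20 ± 1.96), Serpina1a (-1.79 ± 0.47) and the pioneer factor Foxa1 (-1.43 ± 1.18) fell. Albumin (Alb) had a log2 ratio of -0.29 ± 1.04 (adjusted p = 0.460), below 0 on 4 arrays and above on the other 4. Mttp, which loads lipid onto lipoproteins, had a ratio of -0.59 ± 0.48, below 0 on 7 arrays and under the size required for a call (adjusted p = 0.0106). The urea cycle and amino acid metabolism list fell, with 14 of 30 lower, 1 higher and a median of -0.96 (adjusted p = 4.08e-04). Its adjusted p = 0.569 with an estimated correlation. Otc (-2.71 ± 0.65), Agxt (-2.28 ± 1.34), Hpd and Oat (-1.94 ± 1.77) led it.

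Fatty acid oxidation genes were lower, with 14 of 28 down, 1 up and a median of -1.17 (2.25-fold lower; adjusted p = 1.39e-05). The list had an adjusted p = 0.447 with an estimated correlation. The list mean was above 0 in tumors 4 and 6 (0.20 and 0.11). In a list of PPARA targets written after the data were seen, 7 of 19 genes fell and 1 rose, with a median of -0.99, and the control channel varied more between arrays than the tumor channel (median SD 1.17 against 0.71). The controls of arrays 1, 2 and 8 stood apart in several of these genes, such as Cyp4a10 (16.61, 16.55 and 16.58 on the log2 scale, against 10.91 to 14.52) and Pdk4 (10.98, 11.11 and 11.35, against 7.55 to 8.70). On the same arrays the fatty acid oxidation list was lowest (-2.16, -2.29 and -1.82, against -1.19 to 0.20). The controls of arrays 1 and 2 may be the same RNA, and that of array 8 also held skeletal muscle transcripts. The hormone gene Fgf21 (1.81 ± 2.13, above 0 on 6 arrays, adjusted p = 0.0373) lost its call without tumor 3, 4, 5, 6 or 7, at ratios of 1.49 to 1.76 and adjusted p of 0.0693 to 0.0915. The omega-hydroxylase Cyp4a10, one of several near-identical copies, lost it without tumor 1, 2, 3, 7 or 8 (-2.87 to -2.33, adjusted p 0.0726 to 0.103), and its ratio was -3.68 without tumor 4.

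Matrix and stellate cell genes were higher in tumor, with 18 of 38 up, 0 down and a median of 0.86 (1.81-fold; adjusted p = 8.87e-06). The adjusted p = 0.398 with an estimated correlation. The collagens Col1a1 (3.65 ± 1.20) and Col1a2 (3.00 ± 1.21), the protease inhibitor Timp1 (2.69 ± 0.43) and Tgfb2 (2.54 ± 1.00) rose most. Ccn2, a matricellular protein, rose by 1.45 ± 1.09, and Tgfb1 had a log2 ratio of 0.67 ± 0.59 with no call for lack of size (above 0 on 7 arrays, adjusted p = 0.0132). Markers of bile duct cells rose, with 8 of 17 up, 0 down and a median of 1.22 (2.33-fold; adjusted p = 4.55e-04). They had an adjusted p = 0.445 with an estimated correlation. Spp1 (3.34 ± 1.04), Mmp7 (3.21 ± 0.56), Elf3 (2.39 ± 0.42) and Cldn7 (2.28 ± 0.74) rose most.

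Macrophage and myeloid genes moved both ways: 13 of 30 rose and 5 fell, with a median of 0.82 (adjusted p = 0.0153). With an estimated correlation, the adjusted p = 0.447. Cd14 and Trem2 (2.75 ± 1.02) rose, while Clec4f (-3.33 ± 1.11) and Marco (-2.83 ± 2.22), both markers of resident Kupffer cells, fell. Chemokine and cytokine genes were higher, with 13 of 27 up, 1 down and a median of 0.99 (adjusted p = 0.00697). They had an adjusted p = 0.370 with an estimated correlation. Cx3cl1 (2.93 ± 0.88), Cxcl5 (2.83 ± 2.09, well above background in 3 controls), Il33 (2.78 ± 1.71), Ccl8 (2.56 ± 1.55) and the monocyte attractant Ccl2 (2.21 ± 1.02) rose. Interferon response genes were higher, with 9 of 30 up, 1 down and a median of 0.64 (adjusted p = 0.0259; adjusted p = 0.645 with an estimated correlation). Cxcl10 (3.36 ± 1.29), Oasl1 (1.79 ± 1.64), Oas1a (1.78 ± 1.25), one of several near-identical copies, and Ifit2 (1.64 ± 0.98) rose most. The list mean was 1.92 in tumor 7, 1.64 in tumor 8 and -0.25 in tumor 6, and the call was lost without tumor 7 (adjusted p = 0.0720) or tumor 8 (adjusted p = 0.131).

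**Figure D2:**
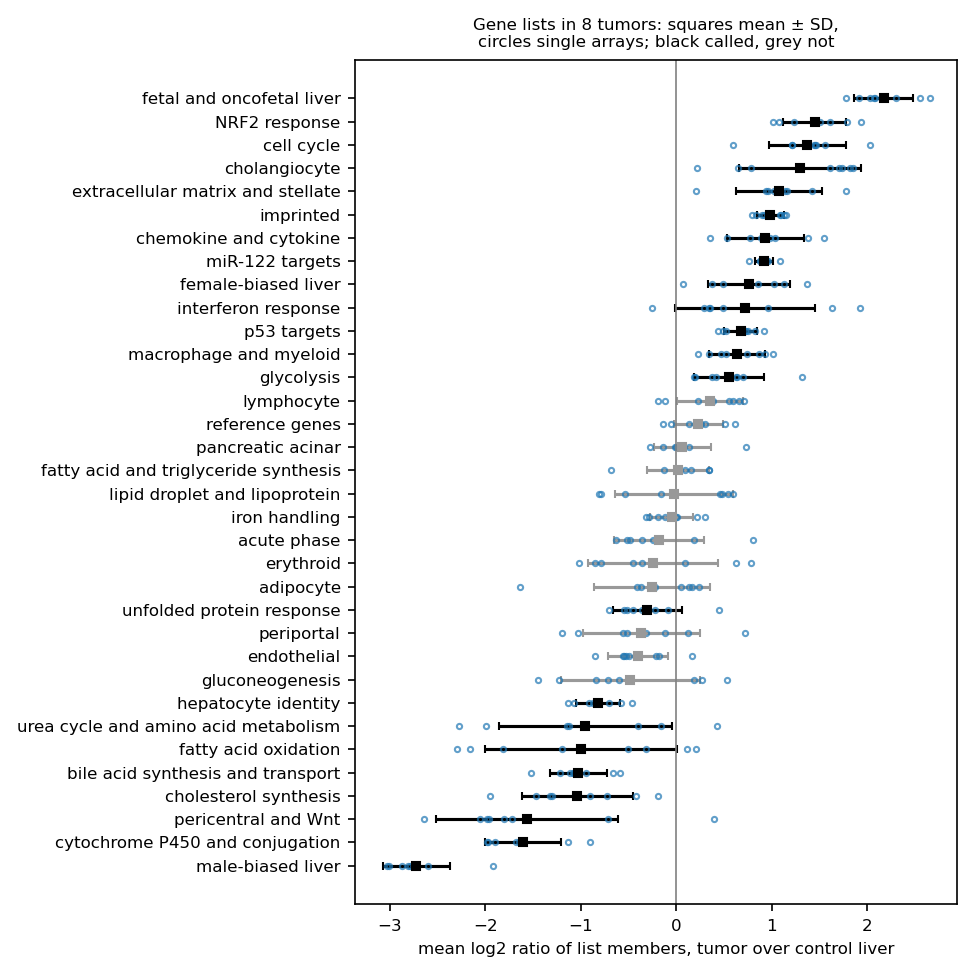
The mean log2 ratio of the members of each of 34 gene lists (horizontal axis) is shown in 8 tumors; circles are single arrays, squares with bars the mean ± SD, and black squares the lists called by camera with its preset correlation. The male-biased list lies lowest, and every circle of the cell cycle, fetal and miR-122 target lists lies above 0.

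Of the 34 lists, 13 were called higher and 9 lower. The list mean lay on the side of the call on all 8 arrays in 17 of them, on 7 arrays for the pericentral, urea cycle, unfolded protein response and interferon lists, and on 6 for fatty acid oxidation. With the correlation between genes estimated from the data, camera called 0 lists, at adjusted p from 0.0938 to 0.783 (8 lists had an unadjusted p under 0.05), while fry, which asks whether members move one way without comparing them with other genes, called 24.

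The other 12 lists were not called. Endothelial genes went both ways, with 2 of 24 up and 7 down (adjusted p = 0.0881), and their median (0.05) differed in sign from their mean (-0.40) and from the test. Cd34 rose by 3.11 ± 0.95, while Clec4g (-3.13 ± 1.06), Oit3 (-2.80 ± 0.67) and Bmp2 (-2.51 ± 0.38) fell; without tumor 2 or tumor 3 the list was called lower (adjusted p = 0.0406 and 0.0360). Among lymphocyte genes, 3 of 21 rose, Jchain (1.89 ± 0.68), Lck (1.30 ± 0.98) and Ptprc (1.12 ± 0.64), and 0 fell (adjusted p = 0.109; 0.0445 without tumor 6). Of the lipid droplet and lipoprotein list, 5 of 24 rose and 3 fell (adjusted p = 0.149): Lpl and Fabp4 (3.72 ± 1.04) were higher and Fabp1 (-2.86 ± 1.505) and Lipc (-2.37 ± 0.46) lower. Its member Apoa4 (1.64 ± 1.73, above 0 on 7 arrays, adjusted p = 0.0245) lost its call without tumor 3, 4, 5 or 6, at ratios of 1.31 to 1.51 and adjusted p of 0.0585 to 0.0625. Fatty acid and triglyceride synthesis genes had 3 of 27 up and 5 down (adjusted p = 0.282), with a median of -0.33 and a mean of 0.02; Mogat2, Scd2 and Agpat1 rose and Acacb fell by 2.54 ± 0.80. Among gluconeogenesis genes, Sds rose (1.38 ± 0.87), Fbp1 (-1.57 ± 1.30) and Slc37a4 (-1.52 ± 0.91) fell, and the other 16 of 19 were not called (list adjusted p = 0.261); without tumors 7 and 8 the list was called lower (median -0.66, adjusted p = 0.0478). Periportal genes had 3 of 22 up and 6 down (adjusted p = 0.288). Pigr (-1.95 ± 0.75), Cps1 (-1.64 ± 1.27) and Cyp2f2 (-1.58 ± 1.36) were lower and Apoa4, also in this list, higher.

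Acute phase genes had 3 of 28 up (2 adjusted over the list alone) and 5 down (adjusted p = 0.599), and the most changed members fell: Apcs (-2.72 ± 1.35), Saa4 (-2.20 ± 1.16), Crp (-2.17 ± 0.96) and Serpina3m (-2.14 ± 0.81). Of 6 adipocyte markers tested, Fabp4 rose and Cfd (-2.54 ± 0.84, well above background in 1 tumor) and Car3 (-1.64 ± 1.01), the latter also abundant in muscle, fell (list adjusted p = 0.288). Of 7 pancreatic acinar genes, Cela1 rose (3.44 ± 0.35) and Amy2a5 fell (-2.56 ± 0.67); the list had an adjusted p of 0.587, a median of -0.05 and a mean of 0.06. Of 6 erythroid genes, Alas2, the first enzyme of heme synthesis in red cells, fell by 2.14 ± 0.59, and the list (adjusted p = 0.608) had a median of 0.26 and a mean of -0.24. Among iron genes, the iron hormone Hamp fell (-2.48 ± 1.02), the transferrin receptor Tfrc rose (1.30 ± 1.06) and the other 20 of 22 were not called (list adjusted p = 0.686). Of 15 reference genes, Gusb (1.57 ± 0.89) and Tfrc rose and 13 were not called (list adjusted p = 0.613).

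The ratio of tumor over control varied most between arrays in Cyp4a14 (log2 ratio -1.79 ± 4.76), followed by Asns, an asparagine synthetase (-0.06 ± 3.69), Cyp4a31 (-2.94 ± 3.62) and Nnmt (-1.56 ± 3.57). The others of the 10 genes with the most variable ratio were Cyp4a10, Dnase1 (2.48 ± 3.10), Ren2 (1.05 ± 3.06), Got1 (-0.87 ± 2.96), Wfdc12 (1.80 ± 2.82) and Pck1 (-2.15 ± 2.80). Either channel can bring this spread: Cyp4a14 had an SD of 3.15 in the control channel and 2.38 in the tumor channel, and Ren2 of 1.81 and 4.11. Of these genes, Cyp4a31, Cyp4a10 and Dnase1 passed the test and the other 7 did not. With the row of the slide as a block, Cyp4a10 (adjusted p = 0.0510) and Cyp4a31 (adjusted p = 0.0501) did not pass, nor did they with arrays 1 and 2 averaged (log2 ratios -2.38 and -2.41, adjusted p = 0.101 and 0.102). Cyp4a31 lost its call without tumor 1, 2, 3, 7 or 8 (-2.95 to -2.38, adjusted p 0.0719 to 0.105) and stood at -3.75 without tumor 4, and Dnase1 lost it without tumor 1, 3, 4, 5 or 6 (1.96 to 2.30, adjusted p 0.0987 to 0.112). Nnmt passed without tumor 8 (-2.44, adjusted p = 0.0397), as did Pck1 without tumor 7 (-2.53, adjusted p = 0.0381) or tumor 8 (-2.70, adjusted p = 0.0168). Without tumors 7 and 8 together, Nnmt (-3.26, adjusted p = 0.00301), Pck1 (-3.25, adjusted p = 0.00657) and Got1 (-2.18, adjusted p = 0.0227) passed.

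Signals varied more between arrays in the tumor channel than in the control channel. The SD across arrays had a median of 0.338 in the tumor channel and 0.188 in the control channel over 14304 genes, and 83.0% of genes had the larger SD in the tumor channel. The median ratio of the SDs was 1.73 (0.79 on the log2 scale). An exact permutation test that swapped the channels within arrays gave p = 0.00781 (2-sided, n = 8), the smallest that its swaps can give. As tumors were always in Cy5, a spread brought by the dye or by dim signal has the same direction, and if control RNA was shared between arrays, its SD is not one between animals.

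Relations between 4 pairs of lists were tested across the 8 tumors, and 0 passed after adjustment over the 4. With median centring in place of loess 2 passed, cell cycle with fetal liver genes (r = 0.753, exact permutation, adjusted p = 0.0478) and matrix with macrophage genes (r = 0.860, exact permutation, adjusted p = 0.0116), and cell cycle with hepatocyte identity had r = 0.717. The cell cycle mean had a Pearson r of -0.0870 with hepatocyte identity (n = 8, exact permutation p = 0.860, adjusted p = 0.860; Spearman rho = -0.143, exact p = 0.752), and r was above 0 without tumor 2 (0.0211) or tumor 8 (0.109). It had r = 0.387 with fetal liver genes (exact permutation p = 0.353, adjusted p = 0.529; rho = 0.548, exact p = 0.171). Matrix genes had r = 0.542 with macrophage genes (exact permutation p = 0.166, adjusted p = 0.529; rho = 0.429, exact p = 0.299). Male-biased genes had r = 0.365 with female-biased genes (exact permutation p = 0.397, adjusted p = 0.529). Their rho was 0.738 (exact p = 0.0458, adjusted p = 0.183). Without the 2 tumors farthest from the median of the first list of each pair, r was 0.187, 0.567, 0.273 and 0.721 in that order. Each row of the slide held 4 arrays, too few for a correlation of its own; with each score centred within its row, r was 0.0414, 0.377, 0.352 and 0.112.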

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

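Every test of explanations in this part was chosen after the result was seen. Of 139 named genes, 18 had an array far from the other 7, as had 5 of 34 lists, where chance gives about 5% of groups; 17 far values, the median ratio of all genes included, lay on array 8.

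In tumor 8, Gpc3 (4.95), Ccn2 (3.75), Atf3 (3.60) and Klf6 (3.29) lay above the other tumors. Erich4 (2.84), Fabp4 (1.51), Elf3 (1.45), Spp1 (1.08), Cd34 (0.98), Cx3cl1 (0.90) and Cdc20 (0.83) lay below them. Slc37a4 stood at 0.61 where all other tumors were below 0, and Car3 at -3.90. The adipocyte (-1.63), fatty acid and triglyceride synthesis (-0.68) and pancreatic acinar (0.73) lists were far from the other tumors, as was the median ratio of all genes (-0.10). Away from array 8, Mup17 (-3.20), Mup18 (-3.65) and the male-biased list (-1.92) were least lowered in tumor 7. Sult2a8 stood at -4.77 in tumor 4, Bmp2 at -3.35 in tumor 3, and Crp (-4.33) and the glycolysis list (1.32) were far in tumor 2.

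The distance of array 8 may come in part from its dim Cy5 signal. Over 3579 bright genes its mean r with the other arrays was 0.605, above the 0.528 over all genes. It lay below the 0.719 to 0.767 of arrays 1 to 6 over the bright genes. Array 7, the next dimmest, had 0.649. Its r was 0.817 with array 2, a brighter array, and at most 0.664 with arrays 1 and 3 to 6. Dimness alone therefore does not account for the low mean of array 7. Array 8 was also closest to arrays 2 (0.708) and 7 (0.691), against at most 0.592 with the others. How much of the distance of array 8 goes with dimness stays open. Liver like the control in the tumor RNA would pull the lowest genes toward 0. The 50 genes lowest in the other arrays had a median of -3.44 on array 8 against -3.71, a share of such liver of at most 9.20%. Liver of the knockout animal outside the tumor was not measured and may differ from the control in these genes, so its share is not bounded. Skeletal muscle RNA in its control liver is a candidate explanation for the muscle genes: their control channel exceeded the other arrays by a median of 3.99, with 34 of 37 genes higher by at least 1, such as Acta1, Myh4 and Tnni2, and the other arrays gave -0.06 to -0.01. The tumor channel of array 8 exceeded the others by 1.11 in the same genes, which leaves open muscle in the tumor, carry-over between samples, or biology of this tumor.

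The fall of male-biased genes might reflect fewer hepatocytes in the tumor RNA, but they lay below hepatocyte identity genes on 8 of 8 arrays. The mean difference was -1.90 ± 0.39 (SD, n = 8, exact permutation p = 0.00781, the smallest that changes of sign can give). That p was fixed in advance, as the male-biased list was taken up for its deep fall. Its means per array (-3.03 to -1.92) were already known to lie below those of the identity list (-1.13 to -0.46). The p therefore carries no weight here. Tumors of female mice would lack Y-linked transcripts, but Ddx3y and Eif2s3y were well above background in the tumor channel on 8 arrays. Lost growth hormone or androgen signals in the tumor, the loss of miR-122 and the state of the animals stay open and were not tested.

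The control channels of arrays 1 and 2 may hold the same RNA: 86 of 12604 genes differed between them by at least 1 on the log2 scale, against 174 to 812 in the other 27 pairs. The bound, fewer than 1 in 2 of the genes of every other pair, was met by a margin of 1 gene, so 2 animals in a like state stay open. The tumor channels of these arrays differed in 1381 genes. Other tumor channels were closer: arrays 5 and 6 differed in 257 genes, 4 and 6 in 353, 4 and 5 in 355, and 2 and 7 in 463. The remaining pairs differed in 687 to 2691. Whether tumors of the close pairs came from the same mouse was not tested, and every test takes the 8 tumors as independent.

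Random signs of the arrays did not reach the number of genes called: of 100 sign patterns of the 8 arrays, 1 called as many, the real one, with 2216 genes against at most 712. The test takes the arrays as independent. A deviation of a shared control or of the dyes has the same sign on every array, so the test cannot exclude it. Probes of chromosome regions without a gene symbol were not part of the gene tests; 80 of 4905 tested were higher and 95 lower.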

How the results depend on the processing

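The results for arrays 7 and 8 left out together, for each row of the slide alone, for arrays 1 and 2 averaged and for row-centred correlations come from tests chosen after the result was seen. Of the called named genes, 118 kept their call under every choice of method set before the data were seen that was run on genes and with each array left out in turn, and 10 lost it at least once, and of 22 called lists 20 kept it, aside from camera with an estimated correlation, which called 0 lists higher and 0 lower. The number of genes higher was 849 in row 2 of the slide alone, against 1630 in row 1 alone, each with 4 arrays, and 4102 with no minimum ratio. Genes lower numbered 1533 with the processed signals and 3594 with no minimum ratio. With 1 array left out, 1293 to 1533 genes were higher and 836 to 902 lower, with 11 to 14 lists higher and 9 to 10 lower. With arrays 1 and 2 averaged, 1305 genes were higher and 839 lower. In row 2 alone 1426 of the 2216 called genes (64.4%) kept their call, and in row 1 alone 1991 (89.8%).

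The glycolysis and interferon lists lost their call with array weights (median log2 ratios 0.51 and 0.43, adjusted p = 0.0993 and 0.179). In row 1 alone the interferon (adjusted p = 0.120) and female-biased lists (adjusted p = 0.133) were not called, while the gluconeogenesis (median -0.70, adjusted p = 0.0275), lipid droplet (median -0.64, adjusted p = 0.0139) and lymphocyte lists (median 0.26, adjusted p = 0.0355) were. The endothelial list was called lower with no filter on dim probes (adjusted p = 0.0481) and in row 2 alone (median -0.35, adjusted p = 0.00623). Among called genes, Cyp4a10, Cyp4a31, Dnase1, Fgf21, Gpc3 and Trib3 lost their call with no filter on dim probes. Cyp4a31, Dnase1 and Fgf21 lost it with median centring, and Cyp4a10, Cyp4a31, Dnase1 and Ccng1 with the processed signals. With array weights Cyp4a10 (log2 ratio -1.54, adjusted p = 0.242), Cyp4a31 (-1.59, adjusted p = 0.237) and Tfrc lost it. Atf4 and Tfrc lost it with the mean of all probes, Cyp4a10 and Cyp4a31 with the slide row as a block, and Dnase1 with an offset of 16 or with scaling. Apoa4 lost it only with an array left out or in 1 row alone. Signs turned in genes that were not called: Alb was 0.18 without arrays 7 and 8 and 0.11 in row 1; Cidec was -0.45 in row 1, Got1 0.015 in row 2 (-2.18 and called without arrays 7 and 8) and Ren2 -0.30 without arrays 7 and 8. Asns was 0.071 with the processed signals, 0.014 with scaling and 1.48 in row 2. With 1 tumor left out Asns ranged from -0.96 to 0.80, above 0 without tumor 3, 4 (0.28) or 6 (0.30).

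The relations of the cell cycle list depended on the normalization. With median centring, r with hepatocyte identity was 0.717 (adjusted p = 0.108) and with fetal liver genes 0.753 (adjusted p = 0.0478), and matrix with macrophage genes had 0.860 (adjusted p = 0.0116), by exact permutation; the cause was not tested. Cell cycle with identity was 0.0211 without tumor 2, 0.109 without tumor 8 and 0.0414 with rows centred. With 1 tumor left out it ranged from -0.173 to 0.109, cell cycle with fetal genes from 0.360 to 0.433, matrix with macrophage genes from 0.381 to 0.6999, and male-biased with female-biased genes from 0.278 to 0.713. The spread ratio of the channels ranged from 0.54 to 0.82 on the log2 scale over its alternatives. Signal over background limits ratios of dim genes, which are drawn toward 0, most of all in the Cy5 channel of array 8.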

Other observations

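All tests of this part were chosen after the result was seen except the correlation of clock genes, which control values of Dbp already seen had prompted. Of 14 sinusoidal endothelial genes, 11 fell and 0 rose, with a median log2 ratio of -1.36 and a list mean below 0 on 8 of 8 arrays; Stab2 (-1.44 ± 0.58), Gpr182 (-2.12 ± 1.17) and Rspo3 (-1.63 ± 0.42) were among them. A further list of 16 endothelial genes left out called members of the fixed list, such as Cd34 and Emcn, which rose, and Ptprb, which fell, so it is not set against these. Of 7 Kupffer cell genes, 6 fell (median -2.33), such as Vsig4 (-2.33 ± 1.16) and Folr2 (-2.21 ± 0.61). Of 12 genes of recruited macrophages 11 rose (median 2.45), such as Cx3cr1 (3.24 ± 1.66) and Gpnmb (2.47 ± 1.16). Members differed in tumor 8: Cx3cr1 (-0.65), Ccr2 (-0.25), Itgax (0.45) and Trem2 (0.67) were low there. In the same tumor Lgals3 (4.15), Chil3 (4.27) and S100a9 (3.33) were high. Some of the latter list are not specific to macrophages: S100a8 and S100a9 are abundant in neutrophils, and Spp1 is in the cholangiocyte list. The difference between these lists was not tested, and the fixed endothelial and macrophage lists hold some of the same genes.

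Of 18 skeletal muscle genes tested, 1 rose and 1 fell, with a median of -0.40 and a mean of -0.16. The list mean was below 0 on 1 array, array 8, whose control channel held muscle transcripts. The median and mean therefore rest in part on that control and do not show a fall in the tumors. In the Y-linked list, 0 of 3 genes were called, with a median of -0.72 and a larger SD in the tumor channel (0.817) than in the control channel (0.0954). Ddx3y (-2.65) and Eif2s3y (-2.63) were lowest in tumor 5; loss of the Y chromosome in part of its cells was not tested.

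Igf2, H19, Hsd3b5 and Elovl3 were the 4 called genes whose channels each had an SD above 0.7 while the ratio had one below 0.4. Hsd3b5, a male-biased steroid enzyme (log2 ratio -3.45 ± 0.21), had channel SDs of 1.69 and 1.78, and Elovl3 (-3.66 ± 0.26) of 1.08 and 0.97. Shared biology of paired animals and an effect of the array were not tested, and the latter would change what these ratios mean. Carry-over between channels by a share common to all genes, if it set these ratios, would hold other genes near these sizes. Afp (6.50 ± 0.92) and Sult2a8 (-6.35 ± 0.77) went well beyond them, which argues against such carry-over for these 4 genes. Carry-over limited to single probes was not tested and would also change what the ratios mean.

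Of the 1204 chromosome regions with 2 or more tested probes, 10 had all of them higher and 6 all lower. On chromosome 15, all 5 tested probes of the region from 32167516 to 32174427 were higher (mean 1.66), as were 3 of 4 of an overlapping region that ends at 32174417. On chromosome 12, 2 of 2 probes between 110842154 and 110883594 (mean 2.02) and 2 of 2 between 110894095 and 110899517 (mean 2.83) were higher. On chromosome 17, 3 of 3 probes between 32044823 and 32045974 were lower (mean -2.73).

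Control livers taken at different times of day are a candidate explanation for the spread of clock genes between control channels. Dbp, which peaks toward evening, ran against the mean of Arntl, Npas2 and Clock across 7 controls, with arrays 1 and 2 averaged (Pearson r = -0.964, exact permutation p = 0.00179; Spearman rho = -0.893, exact p = 0.0123). Without the 2 farthest controls r was -0.891. In the tumor channel r was -0.818 (n = 8, exact permutation p = 0.0166; rho = -0.762, exact p = 0.0368) and -0.353 without the 2 farthest, so it rests on those. Npas2 lay near the floor, and no time of sampling was given. Called genes were few in these lists: 0 of 8 evening genes (median -0.17) and 0 of 3 morning genes (median 0.12).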
